A study of Oryza sativa with 6 samples.

How the data were processed

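Shoots of rice (Oryza sativa) seedlings of the low-cadmium-grain indica cultivar Zhong Jiazao-17 were profiled by paired-end RNA sequencing after 12 days with 0 or 100 µM cadmium chloride in the hydroponic solution. Each group held 3 samples, so 6 libraries were analysed. Poly(A) RNA was selected and the mean insert was 300 bases with a spread of 50, per the labels' protocols. The same protocol text names an adipose tissue, which cannot describe rice shoots and was disregarded. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

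The authors deposited 1 table of 44754 loci with an FPKM value (fragments normalized to transcript length and library size) and a status word, OK or FAIL, for each sample. HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 are named by the submitters' processing notes, without their roles. The notes also name a mouse genome build, whereas the loci lie on 12 chromosomes and 42124 of them carry rice gene identifiers of the LOC_Os form, per the file headers and rows. The build and annotation used are not given in the sources used here, nor is any scaling between samples beyond the FPKM unit or whether counting used the strand. The remaining 2630 loci carry no gene identifier, and 519 loci carry more than 1. Start positions were read as counted from 0, as tables of this layout do, and are given counted from 1. No other per-sample column was present. Entries can share a span, and 1714 of the 20183 tested entries (8.5%) had the same start and end as another tested entry, at 19295 distinct spans in all. Each entry is counted as 1 locus unless stated, and the levels of such entries are uncertain because the source does not say how reads were divided between them.

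The table pairs no identifier with a gene name. Of 41981 distinct identifiers, 0 matched a symbol, synonym or accession of the 39387 genes in the RefSeq table of assembly ASM3414082v1 used for names, and 1 matched when its LOC_ prefix was dropped, at a mean of 0.03 FPKM. The 36 gene lists that had been chosen for the tissue and treatment therefore could not be matched to loci, and neither their tests nor their counts were made. Loci are described by position and level instead, and at most 2 identifiers are printed in each direction.

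FPKM values of 0 with the status FAIL occurred 19 times, in 16 loci, and loci with any failed estimate were left out. The 20183 remaining loci with a mean of at least 1 FPKM over all 6 samples were tested. Values were taken as log2(FPKM + 1), so fold changes are on that scale and understate the change of low loci. Cadmium was compared with control in limma 3.58.1 (R 4.3.3) with an intensity trend in eBayes, two-sided, with Benjamini-Hochberg adjustment over the tested loci and a threshold of 0.05. A second count required a change of at least 2-fold. "Rose" and "fell" describe loci past that adjusted threshold, and SE is the moderated standard error of the log2 change. The test, its thresholds, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The rule for named genes took the 10 largest rises and the 10 largest falls among loci past the threshold whose 2 groups did not overlap. The rule was then cut to 2 in each direction because the files give no names, its requirement of a symbol or description was read as a gene identifier, and the parts of it that call for named genes could not be used. Its last part, the 5 loci of highest mean over all 6 samples, is given by position. All other positions were chosen after their values were seen.

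The test was checked on simulated data with the level and spread of the 20183 loci, 200 of them changed. It recovered 45 of 100 loci changed 2-fold and 77 of 100 changed 4-fold, with 5 false calls. The 200 were drawn only from loci above a lower limit of control level. Far fewer loci changed in the simulation than were called in the data (35.3% of tested loci). The adjusted threshold was therefore stricter there, and these shares do not give the recovery in the data.

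FPKM values carry no library size, so the absolute depth is unknown and no counting interval is given. Among loci with 1 reference transcript, low values of different samples stood in preferred ratios, and the most frequent ratio put the depth of the other 5 libraries at 0.841 to 0.959 of that of control replicate 1, after any scaling by the authors. The peak was weakest for control replicate 3, with 19 loci in its window against 6.5 in the median window. Whole reads could not be recovered for most loci, so no count test was run.

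Samples with the same number were not treated as pairs. Analyses added after the data were examined were the classes of level, the search for runs of neighbouring loci, the loci without identifiers, the comparison of chromosomes, the loci listed at 0 in 1 group and the strength of the response per sample. Runs were 3 or more loci, neighbours among the loci searched, that changed at least 2-fold in the same direction. They were searched among identified loci that overlap no other identified tested locus, and among all tested loci. In the first search, tested loci that had been left out could lie between the members of a run, whatever their change. Overlap with loci without an identifier or below the filter on level was not checked. The number of runs was compared with 10000 shuffles of the loci within chromosomes. Intervals of medians are 95% bootstrap intervals over loci with 2000 resamples, which treat loci as independent although they are not replicates. Fisher's exact tests between sets of loci do the same, so their p-values do not measure the spread between samples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

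The alternatives tried were pseudocounts of 0.1 and 5, no filter on level and a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, eBayes without a trend, sample weights, and each sample left out in turn. Failed estimates kept at 0, loci spanning at least 300 bases and loci with a gene identifier only were added after the data were examined.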

Results

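Transcript levels were compared between shoots of rice seedlings grown for 12 days with 100 µM cadmium and shoots grown without added cadmium, with 3 samples in each group. The question set by the design was which transcripts differ in the shoot under cadmium stress. Positions are those of the deposited table, counted from 1, on a genome build not given in the sources used here. Between 25208 and 26283 of the 44754 loci had a value above 0 in a sample, and 19325 to 20037 reached 1 FPKM. Samples of the same group correlated at 0.946 to 0.964 in control and 0.926 to 0.954 in cadmium across the 20183 tested loci, on the log2 scale, and samples of different groups at 0.82 to 0.888. The first principal component held 63.1% of the variance and separated the groups, with control samples between -64.74 and -58.21 and cadmium samples at 65.74, 79.68 and 39.54 for replicates 1, 2 and 3. The median within-group SD was 0.193 in control and 0.183 in cadmium on the log2 scale.

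Cadmium was accompanied by changes in 35.3% of the tested shoot loci, with more and larger rises than falls. Of 20183 tested loci, 4083 rose and 3041 fell (limma, adjusted p under 0.05). Changes of at least 2-fold were found at 1892 loci that rose and 1044 that fell. The asymmetry grew with the size of the change: 136 loci rose and 20 fell at least 8-fold, and 20 rose and 0 fell at least 32-fold. Among loci that rose the median log2 change was 0.94, and among those that fell it was -0.79. The median over all tested loci was 0.019. Of the 18469 loci whose span is listed 1 time, 3822 rose and 2744 fell, or 35.6%. At 9571 loci the unadjusted p was under 0.05, and at 52.8% of tested loci the values of the 2 groups did not overlap, where chance gives 10%. With any 1 sample left out, and so fewer samples in the test, the number of changed loci was lower, at 4370 to 6364. It was lowest without cadmium replicate 1 (4370) and without control replicate 1 (4654). Under quantile normalization 49.4% of the 7269 changed loci rose, against 57.3% of the 7124 with the deposited scaling.

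**Figure D1:**
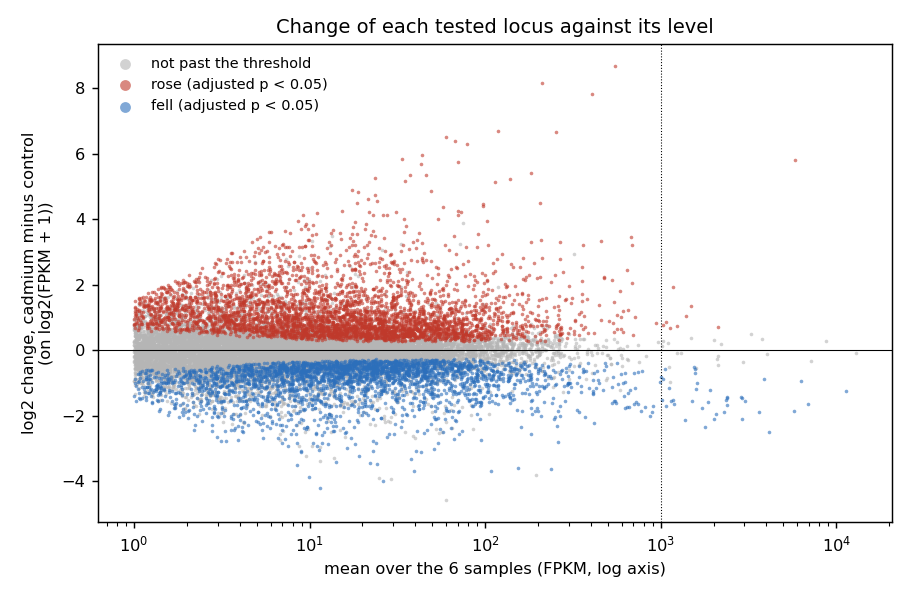
Each point is 1 of the 20183 tested loci, with its mean over the 6 samples in FPKM on a log axis and its log2 change, cadmium minus control, on the log2(FPKM + 1) scale. Loci that rose are red, loci that fell are blue and the rest are grey, and at or above 1000 FPKM (dotted line) 38 loci fell and 9 rose.

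The largest rise on the log2(FPKM + 1) scale was at LOC_Os12g38300, on chromosome 12 from 23514761 to 23515991. It went from 1.647 ± 0.282 FPKM in control to 1098 ± 234 FPKM in cadmium (SD, n = 3 each), a log2 change of 8.68 (SE 0.17, limma adjusted p = 3.32e-05), and all 3 cadmium samples lay between 916.13 and 1361.85. The log2 change was 7.36 with a pseudocount of 5 and 9.29 with a pseudocount of 0.1, the range over all alternatives. LOC_Os07g04930, on chromosome 7 from 2175088 to 2177640, was next. It stood at 0.2267 ± 0.108 FPKM in control and 423.8 ± 347 FPKM in cadmium, where replicate 1 reached 824.94 and replicates 2 and 3 reached 231.95 and 214.54 (log2 change 8.14, SE 0.51, limma adjusted p = 0.00103). The log2 change was 7.52 without cadmium replicate 1 and ranged from 6.07 to 10.09 over all alternatives. The order of the 2 loci turned in some settings. LOC_Os07g04930 was higher with a pseudocount of 0.1 (10.09 against 9.29) and with sample weights (8.80 against 8.65). Its fold of mean FPKM was also higher, at 1870 against 667. That fold is uncertain, since it rests on control values of 0.15 to 0.35 FPKM at unknown depth and on the high value of cadmium replicate 1. The 10 largest rises under the naming rule spanned log2 changes of 5.67 to 8.68 on 5 chromosomes. Their cadmium means ran from 85.5 to 11372.7 FPKM.

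Falls were smaller. The 10 largest under the naming rule spanned log2 changes from -3.99 to -3.02 on 6 chromosomes, with cadmium means of 1.5 to 44.6 FPKM. LOC_Os02g47390, on chromosome 2 from 28928706 to 28932010, went from 203 ± 114 FPKM in control to 14.47 ± 9.03 FPKM in cadmium, a log2 change of -3.68 (SE 0.57, limma adjusted p = 0.00548). The largest fall by the rule, LOC_Os08g14900, on chromosome 8 from 8978308 to 8978703, went from 46.24 ± 28 FPKM to values of 17.71, 0 and 0 in the 3 cadmium samples (log2 change -3.99, SE 1.19, limma adjusted p = 0.043). Its call ended when any 1 library except cadmium replicate 1 was left out, with adjusted p from 0.0765 to 0.123, and the range over all alternatives was 0.00906 to 0.129. Its size was as unsteady, with a log2 change of -5.39 without cadmium replicate 1, -3.28 without either of the other 2 cadmium samples, and -6.19 to -2.49 over all alternatives. The table lists this identifier and span 2 times, and the other entry had a log2 change of -2.35. LOC_Os02g47390 fell further with a pseudocount of 5 (-3.33 against -2.49) and with sample weights (-4.20 against -2.66). It also did so without cadmium replicate 2, cadmium replicate 3 or control replicate 3, and LOC_Os08g14900 fell further in the other alternatives. By mean FPKM, LOC_Os02g47390 fell 14-fold and LOC_Os08g14900 7.83-fold.

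**Figure D2:**
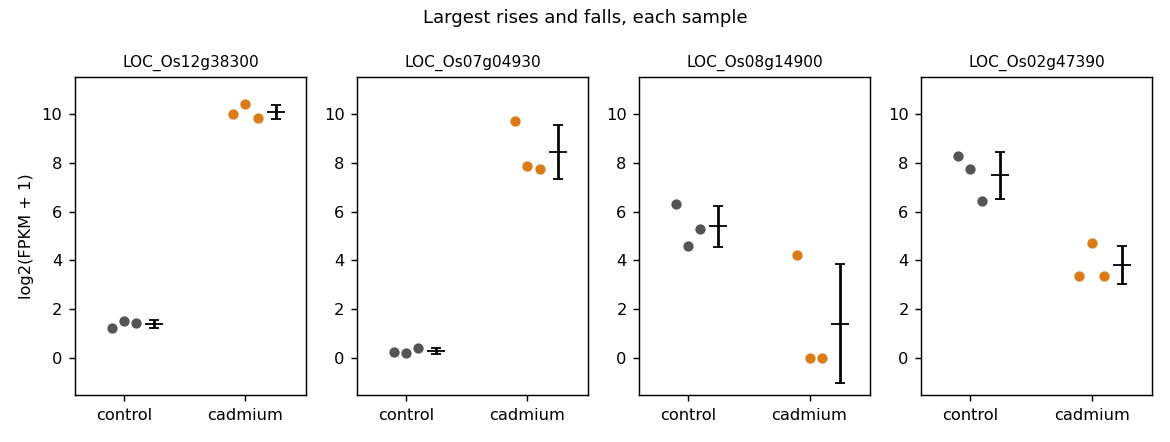
Points give log2(FPKM + 1) of each sample for the 2 loci of largest rise and the 2 of largest fall under the naming rule, and the bars beside them give the mean ± SD of 3 samples. LOC_Os12g38300 rose in all 3 cadmium samples, whereas LOC_Os08g14900 was listed at 0 in 2 of them and at 17.71 FPKM in the other.

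Among the most abundant loci of the shoot, most fell. Of 68 loci with a mean of 1000 FPKM or more, 38 fell and 9 rose, and 21 did not pass the test. Their median log2 change was -0.85 (95% bootstrap interval over loci -1.22 to -0.39), and it was -0.74, -0.84 and -0.83 in cadmium replicates 1, 2 and 3. Together these loci held 214494 FPKM in the mean control sample and 142148 FPKM in the mean cadmium sample. Among 8934 loci at 10 to 100 FPKM, 2168 rose and 1652 fell with a median of 0.02, and among 1043 loci at 100 to 1000 FPKM, 285 rose and 286 fell. Quantile normalization, which gives every sample the same distribution of values, reduced the median of the highest class to -0.225.

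Among the 5 loci of highest mean, 2 passed the test, both lower in cadmium, and neither call held under every alternative. The locus on chromosome 12 from 11262333 to 11278448 went from 15918.5 ± 4435.1 to 6828.8 ± 1959.6 FPKM (log2 change -1.23, SE 0.34, limma adjusted p = 0.0344). Its call ended when any 1 of the 6 samples was left out, with adjusted p from 0.0587 to 0.0941, and the range over all alternatives was 0.0185 to 0.333. The locus on chromosome 8 from 5806458 to 5808458 went from 10387.5 ± 1391.7 to 3353.6 ± 353.6 FPKM (log2 change -1.63, SE 0.2, limma adjusted p = 0.00291). Its call ended without a filter on level, at an adjusted p of 0.0728, and the range over all alternatives was 0.00117 to 0.0728. The other 3, on chromosomes 1, 12 and 9, did not pass the test, with log2 changes of -0.07, 0.29 and -0.32. The total of all FPKM values was 756582 ± 21708 in control and 696884 ± 19037 in cadmium. Loci at 1000 FPKM or more numbered 68 to 79 per control sample and 52 to 59 per cadmium sample, and the 10 highest loci held 11.96% ± 0.84 and 9.67% ± 0.57 of the total. None of these 3 per-sample measures overlapped between groups, and each gave p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 allows.

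**Figure D3:**
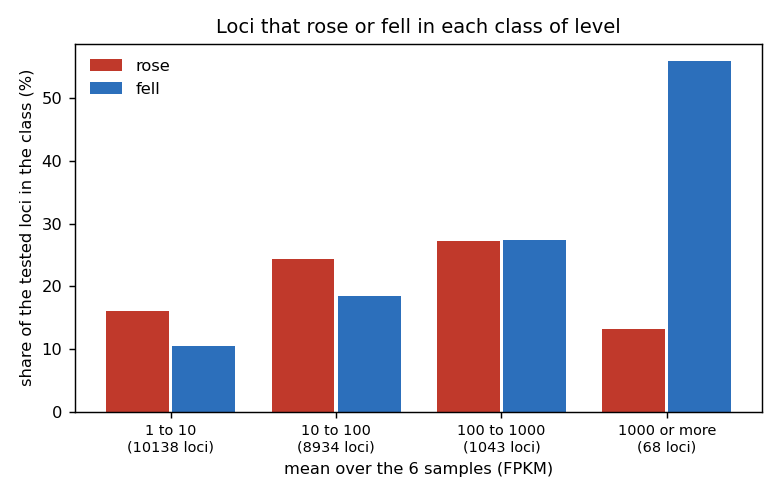
Bars give the share of tested loci that rose (red) or fell (blue), in percent, in 4 classes of the mean over the 6 samples in FPKM, with the number of loci under each class. The share that fell reaches 55.9% in the class of 1000 FPKM or more, where 13.2% rose.

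Some loci were listed at 0 in every sample of 1 group. A value of 0 in all 3 control samples with at least 1 FPKM in all 3 cadmium samples was found at 46 loci, of which 13 had a cadmium mean of at least 10 FPKM and the highest had 134.63. The reverse held for 12 loci, of which 2 had a control mean of at least 10 FPKM, and 3 loci of each set shared their span with another entry. Of the other 9 divisions of the 6 samples into 3 and 3, the highest gave 9 such loci in both directions together, against 58 for the real groups. Each of those divisions mixes cadmium and control samples, so the 46 and 12 loci cannot count in them. No fold is given for the 46 and 12 loci, since their values in 1 group are listed at 0 and the depth is unknown.

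Loci that rose lay in runs along the chromosomes more often than in shuffles of position. A run was 3 or more neighbours that changed at least 2-fold in the same direction. Among 16895 identified loci that overlap no other identified tested locus there were 49 runs, 45 rising and 4 falling, which held 178 loci. Shuffling positions within chromosomes gave 16.1 ± 3.9 runs (SD over 10000 shuffles) and never more than 32 (one-sided permutation p = 0.0001, the smallest these shuffles can give). The 4 falling runs alone, against 1.6 ± 1.2 in shuffles, did not pass this test (one-sided permutation p = 0.074). Among all 20183 tested loci there were 71 runs, 54 rising and 17 falling. The 17 falling runs there exceeded the shuffles, which gave 2.6 ± 1.6 and at most 11 (one-sided permutation p = 0.0001). Entries that share a span lie side by side, and shuffling separates them. The comparison among all tested loci therefore cannot show that neighbouring genes changed together. Of these runs, 8 of the 54 rising and 6 of the 17 falling held the same span listed more than 1 time. The 49 became 16 with a pseudocount of 5, and 33 without control replicate 1, without cadmium replicate 1 or without cadmium replicate 2, and the falling runs ranged from 1 to 10 over the alternatives.

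The run of strongest rise lay on chromosome 12 from 23501361 to 23515991. Its 3 loci rose by log2 changes of 5.82, 6.65 and 8.68, the last of them LOC_Os12g38300, and all 3 passed the test under each of 18 alternatives. The change of 6.65, at the locus from 23512497 to 23513477, was 5.78 without control replicate 3, and with 1 sample left out it reached at most 7.16. The locus at its start, from 23501361 to 23502386, reached 11372.7 ± 2037.5 FPKM in cadmium from 202.7 ± 52.3 FPKM in control, the highest cadmium mean among the 10 largest rises. A run of 4 loci on chromosome 10, from 22575212 to 22608702, rose by 2.73 to 5.21, and 3 loci on chromosome 11 from 22502007 to 22512404 rose by 2.93 to 3.96. On chromosome 7, 2 stretches, from 1890848 to 1987858 and from 21238269 to 21374694, each held 7 neighbouring loci that rose. Among the 4 falling runs, 3 loci on chromosome 1 from 30025249 to 30043938 fell from a mean of 175 to 40.1 FPKM. Whether neighbours in a run are near-identical copies that share reads was not determined, so the levels of single loci in a run are uncertain.

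**Figure D4:**
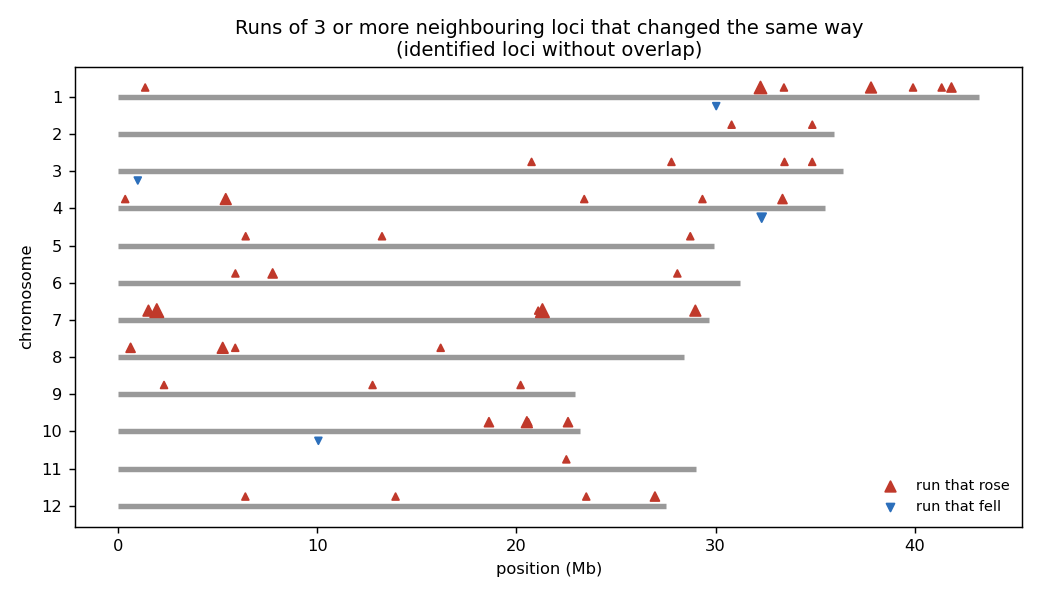
Grey bars are the 12 chromosomes up to the last locus, with position along the chromosome on the horizontal axis (Mb). Triangles mark runs of 3 or more neighbours that rose (red) or fell (blue), larger for longer runs. The loci searched were identified ones that overlap no other identified tested locus. The 45 rising runs lie on all 12 chromosomes and the 4 falling runs on chromosomes 1, 3, 4 and 10.

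By chromosome, loci that rose at least 2-fold were more frequent on chromosome 1, with 333 of 2910 tested loci or 11.4% (odds ratio 1.3 against the other chromosomes, Fisher's exact test, p = 5.65e-05, adjusted p = 0.00136 over 24 tests). Without loci in runs the odds ratio was 1.31 (Fisher's exact test, p = 0.000104). Among identified loci that overlap no other identified tested locus it was 1.3 (Fisher's exact test, p = 0.000188). No other chromosome passed in either direction, with shares of 7.4% to 10.9% that rose and 3.9% to 6% that fell.

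The size of the change was compared between cadmium samples, without a test. At loci called at least 2-fold without the sample in question, the change in that sample was in the median 100% of the change in the other cadmium samples for replicate 1, 105.7% for replicate 2 and 77.8% for replicate 3. These values use the same 3 control samples that entered the calls, so they are not independent of them. Without replicate 3 the count of loci changed at least 2-fold was 3383, against 2936 with it.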

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

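The alternatives with failed estimates kept at 0, loci of at least 300 bases or identified loci alone, and the results on runs and on loci at 1000 FPKM or more, were chosen after the data were seen. The cause was not tested unless stated. Of 18 alternatives, 16 left the count of changed loci within 1.5 times of 7124, and leaving out 1 sample gave 4370 to 6364, with fewer samples in the test. The 2 counts that moved by over 1.5 times were 4370 without cadmium replicate 1 and 4654 without control replicate 1. The count of loci changed at least 2-fold stayed within 1.5 times of 2936 in 17 of 18 alternatives and was 1544 with a pseudocount of 5, which shrinks the fold of low loci by construction. The median log2 change of loci at 1000 FPKM or more kept its sign throughout. It was -0.225 under quantile normalization, which forces equal distributions, -0.761 with sample weights, and -0.863 to -0.735 with 1 sample left out. Samples with the same number did not count as pairs, since the correlations of their deviations from the group means were 0.027, 0.102 and 0.164, not all over 0.1, and control replicate 1 correlated better with cadmium replicate 2 (0.082). The remaining correlations between different numbers ran from -0.155 to -0.006, below those of the same number, so pairing is not excluded. On the second principal component (13.8% of the variance), replicate 3 of control and cadmium stood at 29.86 and 42.62. Replicate 2 stood at -18.79 and -37.57, whereas replicate 1 lay on opposite sides, at -25.11 and 8.98. The block on replicate number gave 6132 changed loci, 2940 of them at least 2-fold. The calls of LOC_Os12g38300, LOC_Os07g04930 and LOC_Os02g47390 held in all 18 alternatives, and that of LOC_Os08g14900 in 9. The median of all tested loci shifted most under quantile normalization, by -0.073. The gene list tests and the count test were not run, because 1 of 41981 identifiers matched the reference, and only without its prefix, and whole reads were not recovered. Unknown depth limits the loci listed at 0, for which no floor could be set without counts.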

Other observations

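The tests of a wrong scale factor, of other sample divisions and of runs by direction were chosen after their results were seen. The real division of the 6 samples called 7124 loci, 2936 of them at least 2-fold, and gave 71 runs, while each of the other 9 divisions called 0 (limma, 205 to 650 loci at an unadjusted p under 0.05). Each of the other 9 divisions mixes cadmium and control samples in both of its groups, so the treatment difference widens its spread and lowers its calls. These divisions therefore do not show what would be called without a treatment effect. In each case 1 of 10 divisions reached the real value, and 10 divisions are too few for a share under 0.05.

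Of 1781 tested loci without a gene identifier, 190 rose and 275 fell, whereas 3893 of 18402 identified loci rose and 2766 fell. The share that rose was 10.7% against 21.2% (Fisher's exact test over loci, p = 2.79e-29), and the share that fell was 15.4% against 15%. At least 2-fold, 144 unidentified loci rose and 177 fell, whereas 1748 identified loci rose and 867 fell. At that threshold the shares that rose lay closer together, and unidentified loci fell more often than identified ones. The 2-fold changes were not compared within strata. Unidentified loci were shorter, with a median span of 751 against 3865 bases, and lower, with a median of 4.28 against 10.68 FPKM. Within strata of span and level, the share that rose was still 7.8 percentage points higher in identified loci (95% bootstrap interval 4.9 to 11.3, 300 resamples). For the share that fell, the same difference within strata was -5.5 points (interval -7.5 to -3.1). Span and level as divided into these strata do not account for the whole difference. The strata were broad and open at their upper ends, so differences in span or level within them are not excluded. How the authors assembled and merged these loci is open, and no biological explanation was tested.

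The fall of the most abundant loci cannot come from 1 wrong scale factor per sample alone, which would move all classes alike. The class at 1000 FPKM or more lay -0.87 log2 units from the class at 10 to 100 FPKM (interval -1.24 to -0.45). Locus span was tested on loci at 300 FPKM or more. In 2 of 3 equally large classes of span these lay below loci at 10 to 100 FPKM with an interval below 0. This argues against span as the whole cause of the difference for loci at 300 FPKM or more. In the class of longest span, with 32 such loci, the difference was -0.62 with an interval of -0.93 to 0.07. The other 2 classes held 137 and 75 such loci, so most lay outside the 68 at 1000 FPKM or more. Span was not tested on those 68 alone. The cadmium treatment itself, as an untested hypothesis, and any scaling by the authors that acted differently by level remain open.

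Runs of neighbouring loci may reflect tandem gene families or regions that respond together, which is a hypothesis. Reads split between overlapping or fragmentary loci were checked by a new search among 16895 identified loci that overlap no other identified tested locus. It found 49 runs in all (at most 32 in 10000 shuffles) and 45 that rose (at most 30). For the rising runs, this argues against runs made by the loci left out. Adjoining fragments with identifiers stayed in, and overlap with unidentified or untested loci was not checked, so split reads are not excluded. Split reads remain a candidate explanation for the falling runs too. There were 17 of these among all tested loci, where shuffles gave at most 11 (one-sided permutation p = 0.0001). Those shuffles separate entries that share a span, so they do not decide between split reads and a joint response. The new search found 4 falling runs, where shuffles gave up to 7 (one-sided permutation p = 0.074). Of the 49, 38 had the same position and number of loci as a run in all tested loci, and the other 11 differed in position or number of loci or had no counterpart there. Reads shared between near-identical neighbours cannot be told apart from a joint response without sequence, and the 7 of the 49 runs whose members changed within 0.5 log2 units of each other do not decide.

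The sample with the highest value among cadmium samples was replicate 2 at 1003 of the 1892 loci that rose at least 2-fold, replicate 1 at 657 and replicate 3 at 232. Among the 20 loci that rose at least 32-fold, replicate 1 was highest at 11.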
